A study of Drosophila melanogaster with 12 samples.

How the data were processed

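Gene expression was measured by RNA sequencing in 12 libraries of Drosophila melanogaster embryos aged 20 to 24 h, 3 libraries in each of 4 groups. Per the labels' protocols, RNA was extracted with a phenol-based reagent, poly(A) RNA was selected, and paired-end reads of 150 bp were sequenced on a NovaSeq X Plus. The labels give no collection date, sequencing batch or sex. They do not say whether the 3 libraries of a group came from separate embryo collections, so the p-values measure only the spread between these samples.

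The deposited table holds raw read counts for 17561 genes, 1 column per library. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, STAR 2.7.11a, featureCounts 2.0.8 and DESeq2 1.40.2 with the dm6 build, without the role or order of each. The strand setting and the treatment of reads with several matches are not stated. Reads of genes that overlap, and of near-identical copies, therefore could not be told apart with certainty. Of the 140 genes named below by the rule, 52 (37.1%) overlap the span of another annotated gene. All 17561 gene numbers matched a gene of the RefSeq table of the same assembly, from which symbols and positions were taken. Per the file headers, the control columns carry the elav null allele over FM7, while the labels give the elav e5 allele over FM7. Both were read as the same libraries, called WT as in the labels.

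Library totals ranged from 22491041 to 97043662 counts. A count of 3 in a library, taken as the limit below which nothing can be said of a gene with 0 counts, corresponds to 0.0309 to 0.133 CPM (counts scaled to library size). A fold change against a group with no counts was computed against 3 counts over that group and is given as a lower bound. Confidence intervals of shares are 95% Wilson intervals. They and the limits cover counting error only, since reads without molecular identifiers are not independent molecules. The number of genes detected was compared after thinning each library to 2e+07 counts.

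Counts were normalised with TMM factors, and 14031 genes that passed filterByExpr were tested with quasi-likelihood F tests in edgeR 4.0.16 under R 4.3.3. All 12 libraries entered 1 model with group as the only term, every test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.595 and the prior degrees of freedom were 5.36. CPM values are TMM-scaled and are given as mean ± SD of 3 libraries, and log2 fold changes with their standard errors (SE) from the model. Each mutant was compared with WT, and each mutant with each other mutant.

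Gene lists were fixed from general knowledge before the data were examined, 25 in all. Each was counted by called members and tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Every printed camera p is adjusted over the lists of a comparison unless stated. Called members were also counted with p-values adjusted over the list alone. The share of X-linked genes among the calls was tested with Fisher's exact test, two-sided, adjusted over the 6 comparisons. Similarity of fold changes between comparisons that share the WT libraries was set beside 20 simulations of unchanged groups against the same WT libraries. The shares of calls that comparisons have in common were set beside 20 simulations each, in which WDd had the mean of another group and genes were drawn independently from the fitted dispersions.

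The genes named were chosen by a rule fixed before the data were examined. It takes elav, fne and Rbp9, and the 8 highest and 8 lowest called genes with a mean of at least 5 CPM, groups that do not overlap and a symbol (5 and 5 between mutants). It adds up to 4 called members of each list, roX1, roX2, Sxl and msl-2, and up to 8 genes called in 1 direction in all 3 mutants. A gene named outside the rule is said to have been chosen after its values were seen. The test was checked on simulated counts with known changes. Of genes changed 2-fold it recovered 38% for elav null, 37% for the double null and 31% for WDd, each against WT. Of genes changed 4-fold it recovered 93%, 92% and 85%. False calls made up 5.76%, 7.19% and 4.13% of the calls. Each of these runs held 14031 genes.

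Alternatives planned in advance were RLE factors, DESeq2 1.42.0, no low-count filter, only the 6 libraries of the groups compared, the replicate number as a block, a 2-fold minimum, and leaving out each library in turn (for lists and named genes, each library of the groups compared). Robust dispersion, the fit without the 3 libraries that detected the fewest genes, and the similarity over genes of at least 5 CPM were added after seeing the data. The fit without those 3 libraries leaves elav null with replicate 2 alone, so no count or p-value of elav null is given from it. Splicing, poly(A) site use and the level of single transcript isoforms, which the series title concerns, cannot be read from counts per gene and were left out.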

Results

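Poly(A) RNA of late Drosophila embryos was counted per gene in 4 groups of 3 libraries. The groups were WT (a control that carries a mutant elav allele over the FM7 balancer), elav null, elav fne double null, and elav WDd. The labels do not describe the WDd allele of elav further. ELAV is a neuronal RNA-binding protein that regulates splicing and poly(A) site choice, and fne and Rbp9 encode its close relatives. Mutant embryos were picked by the absence of the fluorescent protein carried on the FM7 balancer X chromosome. Counts assigned to genes were 97043662, 70538606 and 67841358 in WT replicates 1 to 3 and 83858934, 44286366 and 22491041 in elav null. They were 61618321, 86777299 and 50165513 in the double null and 72103076, 74867886 and 74762460 in WDd. At an equal depth of 2e+07 counts, elav null replicates 1 and 3 and double null replicate 2 detected 11865, 10521 and 11558 genes, and the other 9 libraries 13277 to 15579. Mitochondrial rRNA took 9.54% (95% interval 9.53 to 9.55) and 10.1% (10.08 to 10.1) of the counts in elav null replicates 2 and 3. It took 6.20% to 8.55% in the double null and 0.650% to 3.61% in the other 7 libraries.

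The targeted genes were examined first. elav (CG4262, X: 509235 to 523226, dm6) fell from 112.9 ± 46.1 CPM in WT to 5.01 ± 1.16 in elav null and 5.55 ± 0.566 in the double null (SD, n = 3, edgeR adjusted p = 1.61e-06 and 1.94e-06). In WDd it stood at 163.8 ± 24.2 CPM and did not pass the test against WT (edgeR adjusted p = 1). fne (CG4396, X: 12917477 to 12950417) fell from 195.5 ± 57.7 CPM in WT to 23.3 ± 6.27 in the double null (log2 fold change −3.07 ± 0.51 SE, edgeR adjusted p = 0.000666). In elav null fne reached 173.2 and 242.7 CPM in replicates 1 and 2 but 36.2 CPM in the library labelled elav null replicate 3, a level near that of the double null. Rbp9 (CG3151, 2L: 2954762 to 2968434) was 84.3 ± 10.8 CPM in WT, 31.4 ± 15.2 in elav null, 11.9 ± 1.49 in the double null and 82.6 ± 9.63 in WDd. Its fall passed the test in elav null (edgeR adjusted p = 0.00482) and in the double null (4.17e-05). Of 2 other X-linked genes, chosen after their values were seen, the eye pigment transporter gene w stood at 109.4 CPM in the library labelled elav null replicate 3, 6.43 and 14.7 CPM in replicates 1 and 2, and 89.3 to 101.9 CPM in the double null. Setd3 had no counts in that library or in the double null, and 5.89 and 4.54 CPM in elav null replicates 1 and 2. The elav null allele still gave reads over elav. The gene's span overlaps that of the gene arg and the treatment of such reads is not known, so its residual level is uncertain in either direction.

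**Figure D1:**
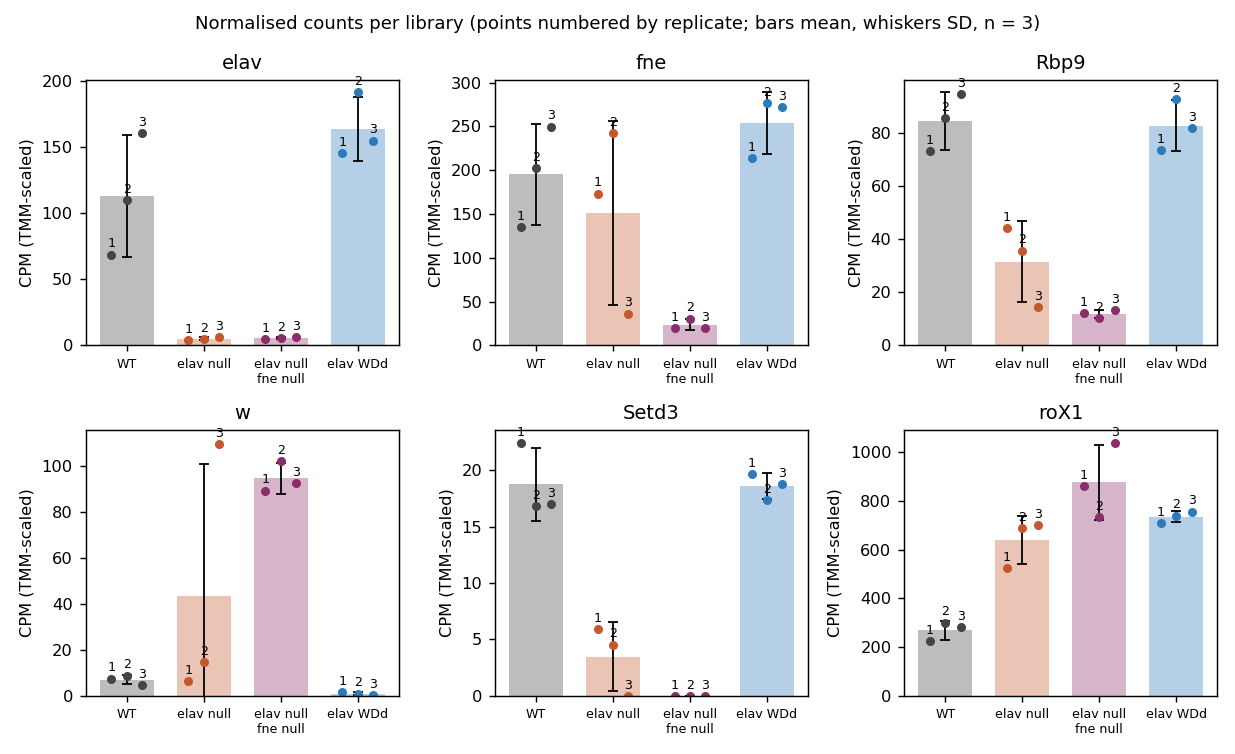
CPM (TMM-scaled) of elav, fne, Rbp9, w, Setd3 and roX1 in the 12 libraries, with points numbered by replicate, bars for the mean and whiskers for the SD of 3 libraries. The library labelled elav null replicate 3 has 36.2 CPM of fne and 109.4 CPM of w, beside the double null libraries, while elav is near 5 CPM in all libraries of both null groups.

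The elav null group was compared with WT to see which transcript levels differed. It includes the library labelled elav null replicate 3, in which fne was near its double null level. The group means may therefore not be those of elav loss alone. Many muscle and cuticle genes were called lower and many stress, immune and digestive genes higher in elav null, while no gene of the synaptic vesicle and active zone list was called. As lists, these 5 passed the camera test at its preset correlation but not with an estimated one (adjusted p = 0.0803 to 0.392). The fit without the 3 libraries that detected the fewest genes leaves elav null with replicate 2 alone, so its tests are not given. bt, which encodes the giant sarcomere kinase projectin, fell from 3443 ± 1080 to 486.5 ± 279 CPM (SD, n = 3), and the muscle actin crosslinker gene Actn from 1177 ± 99.1 to 286.5 ± 182 CPM. In elav null replicates 1 and 2 bt stood at 727.7 and 551.3 CPM and Actn at 479.8 and 261.4 CPM. In the library labelled elav null replicate 3 they stood at 180.5 and 118.3 CPM, within their double null ranges (174.2 to 284.2 and 104.7 to 131.8 CPM). The small heat shock protein gene Hsp26 rose from 20.6 ± 7.09 to 630.3 ± 120 CPM, and Drs, encoding the antifungal peptide drosomycin, from 2.84 ± 1.9 to 168.7 ± 86.5 CPM. In all, 841 genes were higher and 1638 lower of 14031 tested in edgeR, and 4142 had an unadjusted p under 0.05. Fitting only the 6 libraries compared gave 450 higher and 823 lower. The groups did not overlap in 31.2% of the genes, where chance gives 10% for 3 libraries against 3.

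Of 20 muscle genes tested, 16 fell and none rose in elav null (19 lower adjusted over the list alone). Besides bt (log2 fold change −2.82 ± 0.44 SE, edgeR adjusted p = 0.000555) these included GluRIIA, a glutamate receptor subunit of the neuromuscular junction (−2.42 ± 0.25, 2.95e-05), and Zasp52, a Z-disc protein gene (−1.60 ± 0.21, 0.000164). The camera test gave p = 9.9e-12, and adjusted p = 0.217 with an estimated correlation. Of 114 cuticle protein genes, 55 fell, 4 rose and 55 were not called (61 lower and 7 higher adjusted over the list alone; camera p = 1.66e-12, adjusted p = 0.217 with an estimated correlation). TwdlM, a Tweedle cuticle protein gene, fell from 621.1 ± 399 to 1.61 ± 1.75 CPM (edgeR adjusted p = 6.1e-05), Cpr65Ea from 160.2 ± 133 to 1.07 ± 0.406 (0.000184) and Cpr78Cc from 330.8 ± 50.8 to 28.0 ± 7.81 (1.51e-06). The SDs of TwdlM and Cpr65Ea within WT were more than 0.5 of their means. Among 13 genes of transmitter synthesis and transport, 3 fell and none rose in edgeR, and the number was the same adjusted over the list alone. These were Ddc (−2.16 ± 0.33), ple (−1.49 ± 0.31) and ChT (−0.65 ± 0.21), with edgeR adjusted p = 0.000483, 0.00392 and 0.0444. The camera p of that list was 0.0883. ChT lost its call without WT replicate 2 or 3, elav null replicate 1 or the library labelled elav null replicate 3 (log2 fold changes from −0.74 to −0.41). Ddc and ple, which make dopamine, also serve cuticle hardening. Of 20 synaptic vesicle and active zone genes and 20 neuronal transmitter receptor genes, none was called in edgeR or adjusted over the list alone. Their camera p was 0.992 and 0.859. In the synaptic list 1 gene was higher without the library labelled elav null replicate 3, and 2 and 1 were lower without elav null replicate 2 and WT replicate 1.

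Heat shock genes rose in 13 of 14 cases in elav null (14 adjusted over the list alone; camera p = 1.25e-16, adjusted p = 0.0803 with an estimated correlation). Hsp23 rose by a log2 of 4.09 ± 0.52 SE and Hsp26 by 4.94 ± 0.72 (edgeR adjusted p = 0.000124 and 0.000323). The Hsp70 copies, which share reads, also rose, among them Hsp70Bc (6.22 ± 0.87, 0.000241). Of 20 antimicrobial and immune genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; camera p = 4.27e-09, adjusted p = 0.0803 with an estimated correlation). Examples were Drs (5.88 ± 0.58, edgeR adjusted p = 2.23e-05), and, with near-identical copies, AttB (5.40 ± 0.56, 3.5e-05) and BomS1 (5.40 ± 0.63, 7.3e-05). Of 24 midgut protease and digestive genes, 10 rose and 2 fell (11 and 4 adjusted over the list alone; camera p = 9.87e-06, adjusted p = 0.392 with an estimated correlation). The alpha-amylase gene Amy-p, a near copy of Amy-d, rose from 58.4 ± 7.04 to 406.1 ± 36.5 CPM, and the serine protease gene Jon25Biii from 683.6 ± 117 to 2344 ± 125 CPM (edgeR adjusted p = 7.69e-07 and 3.52e-05). Of 15 neuroblast and neural progenitor genes 3 rose, including the neuroblast regulator ase (2.47 ± 0.56, edgeR adjusted p = 0.00717), and 1 fell (6 and 1 adjusted over the list alone; camera p = 0.01, adjusted p = 0.671 with an estimated correlation). The number that rose was 1 without the library labelled elav null replicate 3, WT replicate 1 or WT replicate 2, and 5 without elav null replicate 1. The camera p was 0.187 without the library labelled elav null replicate 3. The level of ase came largely from that library, at 26 CPM against 3.5 and 7.9 CPM in elav null replicates 1 and 2.

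Adult and eggshell transcripts stood out among the genes that were highest in elav null. The yolk protein genes Yp1, Yp2 and Yp3 rose by a log2 of 7.04 ± 1.35, 7.95 ± 1.39 and 6.13 ± 1.05 SE, the eggshell gene Vm26Aa by 9.52 ± 1.73 and the flight muscle actin gene Act88F by 5.99 ± 1.47 (edgeR adjusted p = 0.00241, 0.00122, 0.00109, 0.00256 and 0.012). These levels came largely from elav null replicate 2, in which the summed level of 14 eggshell and yolk genes was 673.7 CPM, against 89.6 CPM in replicate 1, 15.9 CPM in the library labelled elav null replicate 3 and at most 10.2 CPM in every other library. Act88F was no longer called without elav null replicate 2 (3.55). The non-coding RNA genes roX1 and roX2, transcribed in males, rose by 1.25 ± 0.19 and 2.75 ± 0.26 (edgeR adjusted p = 0.000441 and 1.55e-05), Sxl, the female switch gene, fell by 0.71 ± 0.21 (0.0328), and msl-2 was not called (0.45 ± 0.21, 0.165). Sxl lost its call without WT replicate 3, elav null replicate 1 or elav null replicate 2 (from −0.75 to −0.47), and msl-2 was called without the library labelled elav null replicate 3 (0.64). Of the 14 sex-biased and dosage compensation genes 5 rose and 3 fell, with the same counts adjusted over the list alone (camera p = 0.000921, adjusted p = 0.0803 with an estimated correlation). The 5 that rose were roX1, roX2 and the yolk protein genes Yp1, Yp2 and Yp3, counted here again. The upward camera p is therefore no sign of a shift towards male transcripts. The number that fell was 0 without WT replicate 3 and 1 without elav null replicate 1 or replicate 2.

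The other lists held fewer calls in elav null. Among the 3 ELAV family genes elav and Rbp9 fell, with the same count adjusted over the list alone (camera p = 0.000137, adjusted p = 0.0803 with an estimated correlation). Of 88 cytosolic ribosomal protein genes 2 rose, the germline-biased RpL22-like and the near copy RpS14b, and 1 fell (camera p = 0.000665, upward; adjusted p = 0.998 with an estimated correlation; 0.5 without WT replicate 3). RpS14b kept its call without WT replicate 1 but not without any other single library of the pair (0.63 to 0.90). Camera p was over 0.05 for the following lists, given with the genes higher and lower. These were described ELAV and FNE RNA targets (1 and 2), neuronal RNA-binding proteins (1 and 2), ion channels (0 and 3), neuropeptides (1 and 0), axon guidance (1 and 1), sensory neurons (1 and 2), glia (3 and 0), haemocytes (3 and 3), fat body (0 and 0), trachea and chitin assembly (1 and 4), cell death (0 and 2), cell cycle (0 and 0) and oxidative phosphorylation (0 and 5). The glial calls were repo, Mdr65 and Gs2 (edgeR adjusted p = 0.0137, 0.00198 and 0.0372). repo lost its call without WT replicate 2 (0.73), and Gs2 without any single library (0.45 to 0.52) but the library labelled elav null replicate 3. Without the library labelled elav null replicate 3, 855 genes were higher and 1636 lower; the muscle list then had 17 and the cuticle list 50 lower genes. The trachea and chitin list then had 8 of 14 lower (camera p = 0.000827, adjusted p = 0.17 with an estimated correlation), 4 neuropeptide and 3 sensory neuron genes were higher, and 3 axon guidance genes were lower. Respiratory chain genes were lower in 1 case without WT replicate 1 or 2, and in 8 and 3 without WT replicate 3 and the library labelled elav null replicate 3. Without WT replicate 2, 493 were higher and 1131 lower. DESeq2 called 1450 genes higher.

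**Figure D2:**
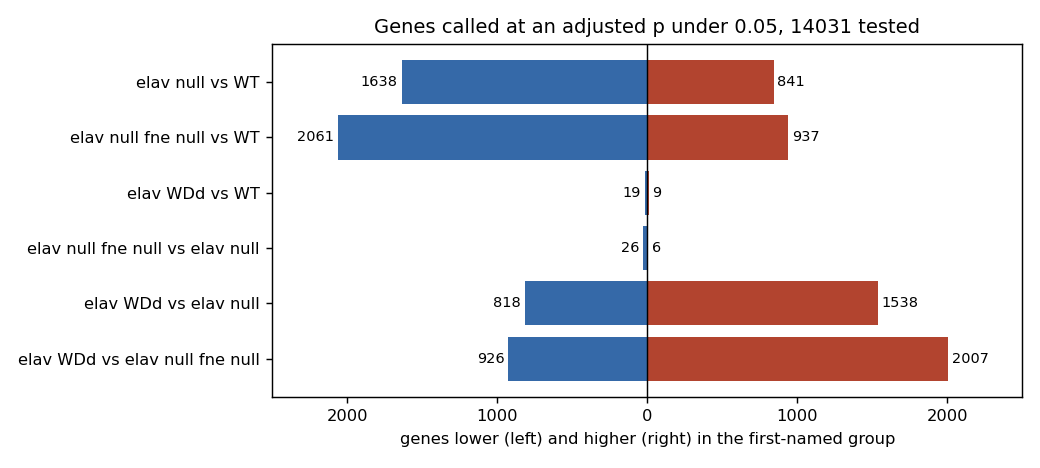
Number of genes called in edgeR (horizontal axis, genes) in each of the 6 comparisons, lower in the first-named group to the left and higher to the right, of 14031 tested. WDd differs from WT in 28 genes and the double null from elav null in 32, while the other 4 comparisons hold 2356 to 2998. The 2 small numbers depend on the libraries fitted. Without the library labelled elav null replicate 3, the double null had 321 genes higher and 726 lower than elav null. In that fit WDd had 24 higher and 54 lower than WT. With only the 6 libraries compared, none differed between the double null and elav null.

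Loss of elav and fne together was compared with WT to see which transcript levels differed. In the double null, some genes of neuronal transmission and many of muscle and cuticle were called lower, and immune, heat shock and neural progenitor genes higher. Their 10 lists passed the camera test at its preset correlation but none did with an estimated one (adjusted p = 0.0662 to 0.706), and the axon guidance, sensory neuron and neuronal RNA-binding lists passed neither. The muscle list did pass with an estimated correlation without the 3 libraries that detected the fewest genes (adjusted p = 0.007) and without the library labelled elav null replicate 3 (0.0448). The transcript of Snap25, a core protein of synaptic vesicle fusion, fell from 40.7 ± 5.2 to 1.72 ± 0.444 CPM (SD, n = 3), and that of the potassium channel gene Shab from 292.2 ± 140 to 41.2 ± 4.85 CPM. The neuroblast gene ase rose from 2.23 ± 0.3 to 28.3 ± 3.79 CPM. In all 937 genes were higher and 2061 lower of 14031 in edgeR, 4464 had an unadjusted p under 0.05, and the groups did not overlap in 42.4% of the genes, where chance gives 10%.

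Among genes of transmitter synthesis and transport, 10 of 13 fell and none rose in the double null (13 lower adjusted over the list alone; camera p = 7.84e-07, adjusted p = 0.29 with an estimated correlation). ChAT, which makes acetylcholine, fell by a log2 of 1.90 ± 0.34 SE, SerT, the serotonin transporter gene, by 1.64 ± 0.29, and Ddc by 2.39 ± 0.33 (edgeR adjusted p = 0.00122, 0.0011 and 0.000193). Of 20 neuronal ion channel genes 11 fell and none rose (12 lower adjusted over the list alone; camera p = 0.00107, adjusted p = 0.616 with an estimated correlation), including Shab (−2.83 ± 0.48, edgeR adjusted p = 0.000742) and Shal (−1.72 ± 0.23, 0.000139). Of 20 synaptic vesicle and active zone genes 8 fell and none rose (9 lower adjusted over the list alone; camera p = 0.00254, adjusted p = 0.616 with an estimated correlation), including Snap25 (−4.56 ± 0.42, edgeR adjusted p = 1.19e-05), Rop (−0.71 ± 0.15, 0.0043) and Csp (−0.82 ± 0.19, 0.00632). Of 20 neuronal transmitter receptor genes 6 fell and none rose (10 lower adjusted over the list alone; camera p = 0.0338, adjusted p = 0.706 with an estimated correlation), including the acetylcholine receptor subunit genes nAChRalpha4 and nAChRalpha7 (edgeR adjusted p = 0.00114 and 0.000965). Of 29 neuropeptide and processing genes 8 fell and none rose (10 lower adjusted over the list alone; camera p = 0.00708, adjusted p = 0.616 with an estimated correlation), including Proc (−2.63 ± 0.46, edgeR adjusted p = 0.000942), Nplp1 (−2.16 ± 0.42, 0.00221) and AstA (−1.33 ± 0.25, 0.00178). Several of these counts depended on single libraries. Ion channel genes fell in 5 cases without WT replicate 3 and in 4, 7 and 6 without double null replicates 1, 2 and 3. Synaptic genes fell in 5 cases without WT replicate 3 or double null replicate 3 and in 4 without double null replicate 1. Neuropeptide genes fell in 5 cases without WT replicate 2, WT replicate 3 or double null replicate 1. Without WT replicate 3 the camera p was 0.0914 for the synaptic, 0.0808 for the ion channel and 0.467 for the receptor list, and without double null replicate 1 it was 0.0781 for the receptor list.

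Neuroblast and neural progenitor genes rose in 8 of 15 cases in the double null and none fell (12 higher adjusted over the list alone; camera p = 2.87e-06, adjusted p = 0.264 with an estimated correlation). Besides ase (log2 fold change 3.66 ± 0.58 SE, edgeR adjusted p = 0.000498) these included mira, an adaptor of asymmetric division (2.18 ± 0.35, 0.000578), and nerfin-1 (2.46 ± 0.37, 0.000332). Without WT replicate 1, 5 rose. The 3 ELAV family genes fell (camera p = 6.58e-08, adjusted p = 0.0476 with an estimated correlation).

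Muscle genes fell in 18 of 20 cases in the double null (19 adjusted over the list alone; camera p = 1.49e-20, adjusted p = 0.143 with an estimated correlation), with bt at a log2 of −3.96 ± 0.47 SE, Actn at −3.33 ± 0.38 and GluRIIA at −3.53 ± 0.26 (edgeR adjusted p = 5.9e-05, 4.51e-05 and 2.61e-06). Of 114 cuticle protein genes 49 fell and 6 rose (52 and 7 adjusted over the list alone, camera p = 2.72e-08, adjusted p = 0.29 with an estimated correlation), with TwdlB at −8.62 ± 1.03 (edgeR adjusted p = 6.47e-05). Vajk4, which is not on that list, stood at −6.57 ± 0.89 (edgeR adjusted p = 0.000157). Immune genes rose in 10 of 20 cases and 1 fell (11 and 1 adjusted over the list alone; camera p = 4.9e-11, adjusted p = 0.0662 with an estimated correlation). Drs rose by 6.71 ± 0.60 and AttC by 7.18 ± 0.88 (edgeR adjusted p = 9.36e-06 and 7.36e-05). Outside the list, the iron carrier gene Tsf1 rose by 6.56 ± 0.77 (edgeR adjusted p = 6.1e-05), and Bomanin copies such as BomBc2 also rose. Heat shock genes rose in 11 of 14 cases (12 adjusted over the list alone; camera p = 9.44e-09, adjusted p = 0.264 with an estimated correlation), with Hsp26 at 4.18 ± 0.69 (edgeR adjusted p = 0.000666). Digestive genes rose in 7 of 24 cases and fell in 2 (9 and 5 adjusted over the list alone; camera p = 0.000587, adjusted p = 0.565 with an estimated correlation), with Amy-p at 3.01 ± 0.16 (edgeR adjusted p = 5.01e-07). The number that fell was 0 without WT replicate 2, double null replicate 1 or double null replicate 3, and 4 without WT replicate 3. Setd3 had no counts in the double null and 18.7 ± 3.2 CPM in WT, at least 1280-fold lower (edgeR adjusted p = 0.000241). It was already at 5.89 and 4.54 CPM in elav null replicates 1 and 2. Whether loss of these genes or another difference between the stocks accounts for it was not tested.

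Respiratory chain genes fell in 37 of 76 cases in the double null and 1 rose (53 and 1 adjusted over the list alone; camera p = 2.66e-06, adjusted p = 0.616 with an estimated correlation). Examples were SdhA, a subunit of succinate dehydrogenase, from 393.8 ± 27 to 190.0 ± 21.7 CPM, and the complex I gene ND-49 from 304.5 ± 31.5 to 147.1 ± 27.1 CPM (edgeR adjusted p = 0.000699 and 0.00163). Without WT replicates 1 or 2 the number that fell was 14 or 19, and without double null replicates 1, 2 or 3 it was 21, 13 or 18. roX1 rose by a log2 of 1.71 ± 0.19 SE and roX2 by 2.49 ± 0.25 (edgeR adjusted p = 4.17e-05 and 2.22e-05), while Sxl and msl-2 were not called (−0.60 ± 0.21 and 0.21 ± 0.20, edgeR adjusted p = 0.057 and 0.556). Sxl was called lower without WT replicate 1 or double null replicate 2 (−0.72 and −0.76). The sex-biased list had 3 genes higher and 1 lower (camera p = 0.0275, 0.0694 without WT replicate 1; adjusted p = 0.264 with an estimated correlation), and the ribosomal protein list 2 and 1 (camera p = 0.000397, upward, 0.28 without WT replicate 3; adjusted p = 0.706 with an estimated correlation). Camera p was over 0.05 for the RNA targets (1 higher and 3 lower), neuronal RNA-binding proteins (1 and 3), axon guidance (2 and 2), sensory neurons (1 and 2), glia (2 and 1), haemocytes (2 and 3), fat body (0 and 1), trachea (1 and 1), cell death (2 and 1) and cell cycle (0 and 0). Without WT replicate 2, 602 genes were higher and 1515 lower in edgeR. DESeq2 called 1690 higher. With RLE factors 1249 were higher and 1696 lower, so that 42.4% of the calls were higher against 31.3% with TMM, and the median log2 fold change of all genes was 0.10 against −0.03.

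**Figure D3:**
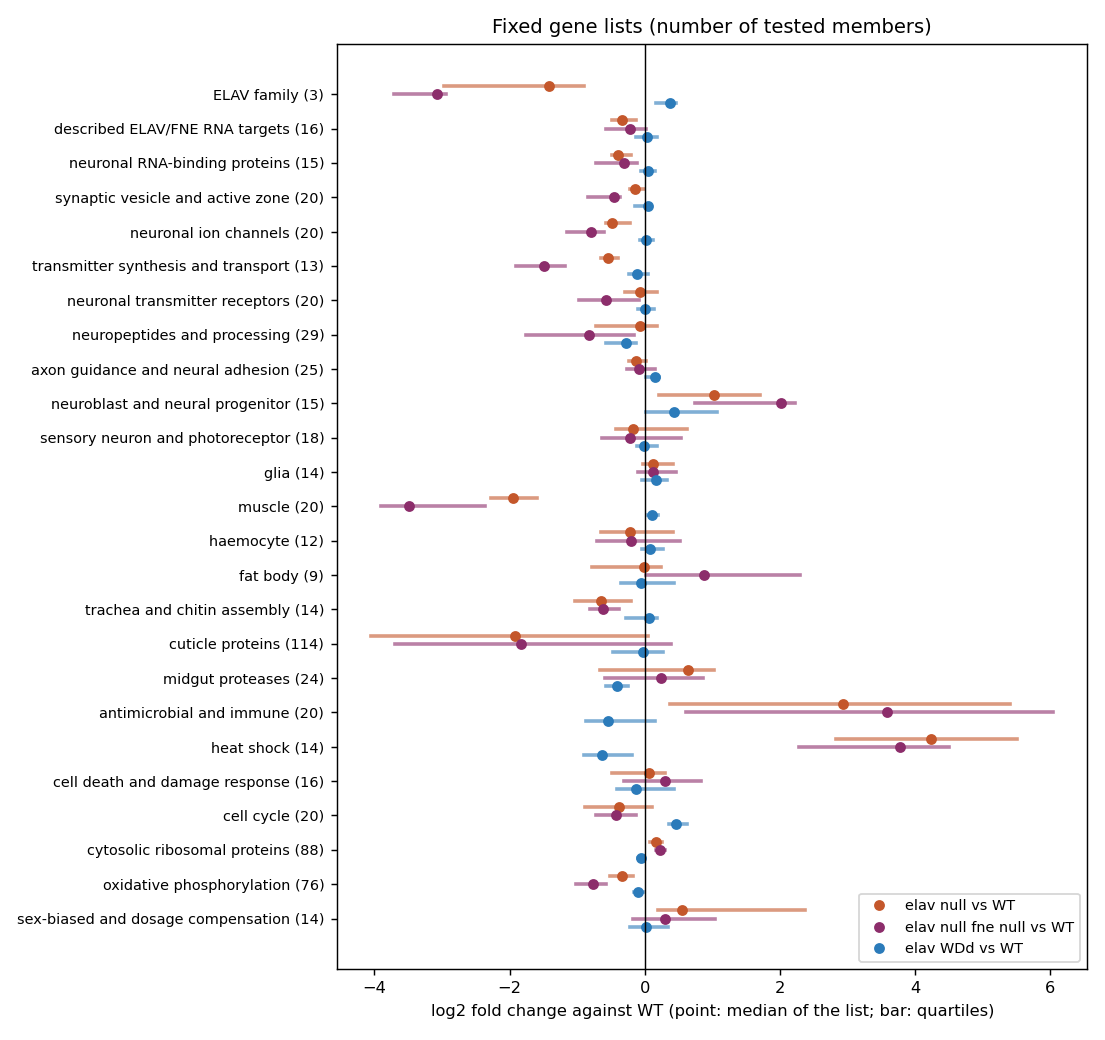
Median (point) and quartiles (bar) of the log2 fold change against WT of the tested members of each of the 25 fixed gene lists, for the 3 mutant groups. The muscle list lies at −1.95 in elav null, −3.48 in the double null and 0.11 in WDd, and the heat shock list at 4.24, 3.78 and −0.63.

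The WDd allele was compared with WT to see which transcript levels differ with this allele. Few genes passed the test: 9 genes were higher and 19 lower of 14031 in edgeR, with 644 at an unadjusted p under 0.05 and groups that did not overlap in 14.3% of the genes, where chance gives 10%. Hr38, a nuclear receptor gene induced by neuronal activity, fell from 53.4 ± 40.7 to 5.81 ± 1.2 CPM (SD, n = 3), the transcription factor gene Ets21C from 53.7 ± 25 to 7.16 ± 0.785 CPM, and Socs36E, a brake on JAK/STAT signalling, from 179.1 ± 66.2 to 60.8 ± 8 CPM. The gluconeogenesis gene Pepck2 rose from 67.8 ± 11.1 to 170.7 ± 12.7 CPM, and the maltase gene Mal-A8 from 15.2 ± 5.45 to 44.7 ± 7.65 CPM. The lipid synthesis gene ATPCL fell from 305.5 ± 116 to 117.4 ± 5.33 CPM. The edgeR adjusted p of these 6 genes was 0.033, 0.00256, 0.0261, 0.0315, 0.0322 and 0.0459. Ets21C passed the test without each of the 6 libraries in turn. Hr38, Socs36E and ATPCL each lost the call without WT replicate 2 or 3 or any 1 of the 3 WDd libraries, with log2 fold changes from −3.27 to −2.44, −1.67 to −1.35 and −1.40 to −1.06 in those fits. Pepck2 lost it without any 1 of the 6 libraries (1.21 to 1.44), and Mal-A8 without any but WT replicate 3 (1.32 to 1.68).

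elav, fne and Rbp9 were not called in WDd (log2 fold change 0.54 ± 0.26, 0.38 ± 0.47 and −0.03 ± 0.30 SE, each with an edgeR adjusted p of 1). Of the members of the 25 lists, only Ets21C, in the cell death list, and roX1 and roX2 were called. Adjusted over the list alone, 3 cell death, 2 immune, 1 glial and 1 cuticle gene were lower. By the same count 3 sex-biased genes and 1 neuroblast gene were higher. roX1 rose by a log2 of 1.45 ± 0.19 and roX2 by 1.62 ± 0.25 (edgeR adjusted p = 0.00639 and 0.0185), and Sxl and msl-2 were not called (−0.34 ± 0.21 and 0.81 ± 0.20, edgeR adjusted p = 1 and 0.223). roX1 lost its call without WDd replicate 1 (1.47), and roX2 without any single library (1.41 to 1.68) but WT replicate 1. None of the muscle, synaptic, ion channel or transmitter synthesis genes was called in edgeR, where the medians were 0.11, 0.04, 0.03 and −0.12. The camera p of the downward lists was 9.19e-06 for midgut, 0.00041 for immune, 0.00662 for heat shock, 0.00662 for neuropeptide and 0.015 for cell death genes. That of the upward lists was 0.00041 for cell cycle, 0.012 for neuroblast, 0.00662 for axon guidance and 0.000402 for sex-biased genes. With an estimated correlation the lowest of these was adjusted p = 0.0728, for the sex-biased list, and the adjusted p was 0.539 to 0.705 for the others. The camera p of 7 of the 9 lists passed 0.05 when a single library was left out. Without WT replicate 1 it was 0.0695 for the immune and heat shock lists, 0.282 for the neuroblast list and 0.954 in the opposite direction for the axon guidance list. Without WT replicate 2 it was 0.081 for the heat shock list, and without WT replicate 3 it was 0.124 for the cell cycle list. Without WDd replicate 1 it was 0.131 for the neuroblast list. Without WDd replicate 2 it was 0.815 for the cell cycle, 0.074 for the axon guidance and 0.162 for the neuropeptide and cell death lists, and without WDd replicate 3 it was 0.39 for the heat shock list. The other lists had camera p over 0.05.

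Of the 28 genes called in WDd, 14 were X-linked (50% against 15.7% of the genes tested, odds ratio 5.4, 95% interval 2.38 to 12.2, Fisher's exact test adjusted p = 0.000143). The X-linked calls included the pigment gene y (−1.13 ± 0.20 SE), the secreted phospholipase gene GIIIspla2 (−1.39 ± 0.22), Rhp (−1.04 ± 0.18) and Ldsdh1 (1.16 ± 0.19), with edgeR adjusted p = 0.0366, 0.0242, 0.0359 and 0.0252. y and Rhp lost the call without any 1 of the 6 libraries (−1.24 to −0.97 and −1.10 to −0.93), GIIIspla2 without any but WT replicate 3 (−1.48 to −1.25) and Ldsdh1 without any but WT replicate 1 (0.99 to 1.30). The neighbouring genes CG3588 and CG14419, chosen after their values were seen, were nearly absent: CG3588 (X: 2919770 to 2924426) had 160033 counts in WT and 292 in WDd, and CG14419 (X: 2885186 to 2885914) had 18856 and 34. Between w and CG3603, the genes CG14416, CG14417, CG14418 and CG3526 had 40, 97, 134 and 73 counts in WT and 0 in WDd. Others there kept some counts in WDd, such as CG32793 (95 against 352 in WT) and CG14420 (16 against 31). The gene kirre, whose span covers this stretch, kept 4174 against 5737. The flanking genes CG32795 and CG3603 kept 37770 and 1943 counts in WDd against 38560 and 2147 in WT. The number of calls depended on single libraries. Without WT replicates 1, 2 and 3 there were 14, 2 and 4 genes higher and 21, 7 and 12 lower, and without WDd replicates 1, 2 and 3 there were 0, 2 and 2 higher and 4, 3 and 6 lower. Without the library labelled elav null replicate 3, which is in neither group, 24 were higher and 54 lower, and without double null replicate 3 there were 8 and 11. DESeq2 called 58 higher and 97 lower, and without the 3 libraries that detected the fewest genes, all of them in other groups, edgeR called 24 and 63.

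**Figure D4:**
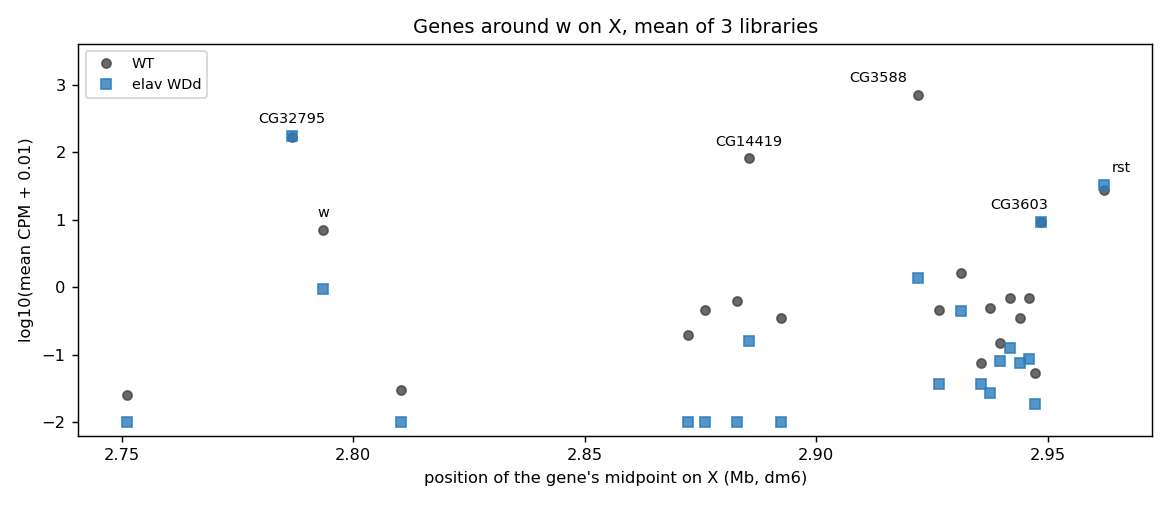
Mean level of each annotated gene around w on X (horizontal axis, gene midpoint in Mb, dm6) in WT and WDd, as log10 of CPM plus 0.01, for 3 libraries each. CG14419 and CG3588 are high in WT and low in WDd, while CG32795 and CG3603 at the sides are alike.

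Loss of fne in addition to elav was read from the double null against elav null, which includes the library labelled elav null replicate 3. With that library 6 genes were higher and 26 lower of 14031 in edgeR, and 1836 had an unadjusted p under 0.05. Fitting only the 6 libraries compared gave none higher or lower (1092 at an unadjusted p under 0.05), the replicate block 0 and 2, and RLE factors 1 and 6. Of the genes named here, only Snap25 was called with the block or RLE factors, and none with the 6 libraries alone. Snap25 fell from 24.6 ± 15.1 to 1.72 ± 0.444 CPM (SD, n = 3, log2 fold change −3.84 ± 0.41 SE), the neuropeptide gene Proc from 53.4 ± 36.2 to 8.09 ± 1.38 CPM and fne from 150.7 ± 105 to 23.3 ± 6.27 CPM (edgeR adjusted p = 0.00444, 0.0409 and 0.0499). Tollo, encoding a Toll-like receptor, rose from 14.4 ± 3.33 to 36.5 ± 2.93 CPM, and Arc2, a capsid-like gene, from 1.80 ± 0.602 to 7.14 ± 1.34 CPM (edgeR adjusted p = 0.0495 and 0.0452). elav was at 5.55 and 5.01 CPM (edgeR adjusted p = 0.877), and Rbp9 was not called (−1.40 ± 0.30, edgeR adjusted p = 0.0777). The yolk genes Yp2 and Yp3, whose level was high in elav null replicate 2, were lower in the double null (edgeR adjusted p = 0.0479 and 0.0409). Without double null replicate 2 or 3 Snap25 lost its call (−4.01 and −3.66). fne, Tollo and Yp2 lost theirs without elav null replicate 1 or 2 or any 1 of the double null libraries, and Proc, Arc2 and Yp3 without elav null replicate 1 or any 1 of the double null libraries. In those fits fne was at −2.92 to −2.16, Tollo at 1.24 to 1.41, Yp2 at −8.50 to −5.43, Proc at −2.86 to −2.60, Arc2 at 1.90 to 2.15 and Yp3 at −6.71 to −6.12. Rbp9 was called without the library labelled elav null replicate 3 (−1.73).

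Without the library labelled elav null replicate 3, 321 genes were higher and 726 lower in the double null than in elav null. Muscle genes then fell in 16 of 20 cases, transmitter synthesis genes in 9 of 13, receptor genes in 9 of 20, neuropeptide genes in 13 of 29, synaptic genes in 7 of 20, ion channel genes in 4 of 20 and respiratory chain genes in 11 of 76, and 6 of 15 neuroblast genes rose. The camera p of these 8 lists was 5.97e-22, 1.94e-17, 9.79e-09, 1.22e-14, 3.39e-11, 1.4e-05, 4.26e-09 and 2.39e-07. The corresponding values with an estimated correlation were adjusted p = 0.0612, 0.0493, 0.34, 0.0493, 0.298, 0.501, 0.409 and 0.135. With all 12 libraries none of them passed with an estimated correlation (adjusted p = 0.337, 0.337, 0.381, 0.337, 0.337, 0.523, 0.437 and 0.337). In that fit of all libraries the numbers lower were 0, 1, 0, 2, 1, 1 and 0 in the same order, and no neuroblast gene rose. Adjusted over the list alone they were 16, 8, 8, 5, 5, 3 and 0, and 5 neuroblast genes rose. Leaving out elav null replicates 1 or 2 gave 1 or 64 genes higher and 2 or 23 lower. Leaving out double null replicates 1, 2 or 3 gave none higher and 2, 0 or 0 lower. Leaving out a library of another group also moved these numbers: without WT replicates 1, 2 or 3 there were 3, 0 or 2 higher and 8, 2 or 8 lower, and without WDd replicates 1, 2 or 3 none higher and 1, 3 or 3 lower. DESeq2 called 257 higher and 320 lower.

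WDd was set directly against each null group, since a call in one mutant and not in another does not test their difference. Against elav null, WDd had 1538 genes higher and 818 lower of 14031 in edgeR. Muscle genes were higher in WDd in 18 of 20 cases and cuticle genes in 54 of 114, with 4 lower (camera p = 1.48e-13 and 4.01e-14; adjusted p = 0.166 and 0.158 with an estimated correlation). Heat shock genes were lower in 13 of 14 cases, immune genes in 12 of 20 and digestive genes in 12 of 24 (camera p = 1.02e-19, 2.11e-12 and 3.48e-11; adjusted p = 0.0669, 0.0669 and 0.158 with an estimated correlation). elav was higher in WDd by a log2 of 5.05 ± 0.31 SE, Rbp9 by 1.39 ± 0.30 and TwdlM by 8.24 ± 0.96, and AttC was lower by 7.88 ± 0.97 (edgeR adjusted p = 8.74e-07, 0.00584, 7.45e-05 and 0.000105). Leaving out WDd replicate 3 gave 957 higher and 486 lower, and the number lower was 528 and 535 without WDd replicates 1 and 2. DESeq2 called 1552 lower.

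Against the double null, WDd had 2007 genes higher and 926 lower of 14031 in edgeR. Transmitter synthesis genes were higher in WDd in 11 of 13 cases, ion channel genes in 10 of 20, receptor genes in 9 of 20, synaptic genes in 7 of 20, respiratory chain genes in 26 of 76 and muscle genes in 18 of 20. The camera p of these 6 lists was 3.07e-06, 0.000172, 0.0115, 0.00126, 2.72e-05 and 1.88e-22. With an estimated correlation the values were adjusted p = 0.329, 0.656, 0.656, 0.656, 0.656 and 0.12. Neuroblast genes were lower in 6 of 15 cases, and immune genes in 12 of 20 (camera p = 0.000189 and 3.46e-14; adjusted p = 0.332 and 0.0372 with an estimated correlation). elav, fne and Rbp9 were higher in WDd by a log2 of 4.88 ± 0.31, 3.44 ± 0.52 and 2.79 ± 0.32 SE (edgeR adjusted p = 8.89e-07, 0.000358 and 4.69e-05). The number lower was 557 without WDd replicate 3 and 615 without double null replicate 1, 1552 without the 3 libraries that detected the fewest genes, and 1874 in DESeq2. With RLE factors 1606 were higher and 1247 lower, so that 56.3% of the calls were higher against 68.4% with TMM, and the median of all genes was −0.13 against 0.01.

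The elav null and double null changes were compared gene by gene. Both called 658 of the same genes higher and 1301 of the same genes lower, and none in opposite directions, where independent lists would share 56.2 and 241. These counts include the library labelled elav null replicate 3, in which most genes that set the 2 groups apart lay closer to the double null. Across genes, which are not independent replicates, the correlation of the fold changes was 0.588, against 0.317 in 20 simulations of unchanged groups that share the WT libraries, and the covariance was 1.65 against 0.297. The correlation was 0.87 over 8424 genes with a mean of at least 5 CPM (0.42 simulated). Over all genes it was 0.303 without elav null replicate 2 and 0.492 without the library labelled elav null replicate 3. The 3 WT libraries cannot be split into 2 parts of at least 2, so part of the excess may come from shared WT libraries. For elav null and WDd the correlation was 0.0988 against 0.32 simulated and the covariance 0.161 against 0.299. It was 0.262 without WT replicate 1, 0.255 without WT replicate 3 and 0.158 without elav null replicate 2. For the double null and WDd it was −0.00403 against 0.326 simulated, with a covariance of −0.00529 against 0.299. It was above 0 without WT replicates 1 or 3 (0.191 and 0.299), double null replicates 1 or 3 (0.0208 and 0.0451) or WDd replicate 3 (0.00869), and none of these single-library values exceeded the simulated one. The simulated groups lacked the changes of the null groups, which widen the spread of fold changes and so lower a correlation. Over genes of at least 5 CPM the covariances of the WDd pairs were 0.0327 and 0.0315, against 0.0443 and 0.0449 simulated. The simulations therefore cannot show that WDd was less like the null groups than an unchanged group. All 3 mutants shared 20 calls in 1 direction, 9 higher and 11 lower, of which 11 were X-linked. In 20 simulations without any WDd change, which share the WT libraries, 6 to 13 of the 28 genes of lowest p in WDd were shared in this way. Among the 20 shared calls roX1, roX2, Mal-A8, Pepck2 and Ldsdh1 rose, and y, Hr38, Ets21C, Socs36E, GIIIspla2 and Rhp fell. In WDd each of these calls but that of Ets21C depended on single libraries, as given above.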

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

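The tests of the library labelled elav null replicate 3, of the X-linked share in WDd, of mirrored calls and of older age, and the simulations beside them, were chosen only after the result was seen, as was reading the X share and the stage lists on the null groups apart from WDd. With 3 libraries in each group no test was made for a single library far from its group, and no sample was left unused by the comparisons. On the first 2 principal components (35.1% and 19.1% of the variance) the library labelled elav null replicate 3 stood at 187 and 133, and the other elav null libraries at 51.4 and −18.7 and at 27.5 and −63.8. The 3 patterns below were weighed because they bear on what the comparisons mean.

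In the library labelled elav null replicate 3, fne, w and Setd3 stood near their double null levels. Other named genes did not. Arc2 (1.25 CPM) and Tollo (18.2 CPM) lay nearer to the other elav null libraries, and SerT (17.3 CPM) and Snap25 (10.1 CPM) lay between the groups. Low depth is argued against as the cause of its low fne: 780 counts were found where its depth predicts 4479, or 17.4%, and elav null replicate 1, which also detected few genes, had 173.2 CPM. Fewer neurons is argued against as the whole cause: the 20 synaptic genes had a median log2 ratio of −0.605 to the other elav null libraries (quartiles −0.836 and −0.473) and 4 other neuronal lists −0.646 (ion channels), −1.45 (transmitter synthesis), −0.627 (receptors) and −0.647 (neuropeptides), while fne stood at −2.48, though 1, 2, 6, 2 and 9 genes of these 5 lists fell to within 1 of it or further, so some loss of neurons stays open. Embryos of the double null genotype in this library are a candidate explanation: without it 1047 genes were called between the groups, and of the 943 with a mean of at least 5 CPM, 829 (87.9%) lay closer in it to the double null, 241 of 268 higher and 588 of 675 lower. For a mixture the genes point both ways. Setd3 had no counts. CG1304, chosen after its values were seen, stood at 0.88 CPM against 132.9 and 72.45 CPM in elav null replicates 1 and 2. SerT and Snap25, however, lay between the groups. A single wrong label, a mixture and a second mutation in the stock stay open, and no biological explanation was tested.

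Of the 28 genes called in WDd against WT, 14 were X-linked. A deletion beside w, where neighbouring genes had no or few counts in WDd, is argued against as the whole cause: without the genes from w to CG17959, which hold 2 of the calls, the odds ratio was 4.65 (95% interval 1.96 to 10.9). A difference from WT shared by the mutants may account for much of it, since 11 of the 14 X-linked calls, and 9 of the 14 others, were also called in the same direction in elav null and the double null, where the WT libraries the comparisons share gave at most 7 of the 14 X-linked genes of lowest p, and 13 of the 28 genes of lowest p, in 20 simulations without any WDd change (genes drawn independently). Whether that is the sex make-up or the FM7 balancer of WT was not separated by this test, and the 28 calls changed with single libraries, to 4 without WDd replicate 1, 5 without WDd replicate 2, 8 without WDd replicate 3, 9 without WT replicate 2, 16 without WT replicate 3 and 78 without the library labelled elav null replicate 3. An effect of the WDd allele on these genes stays open, untested.

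Among the calls of the null groups against WT, roX1 and roX2, transcribed in males, were at least 2.37-fold higher in every mutant group, which a different sex make-up would give, although the labels state no sex. Mutants were picked by the absence of the FM7 X chromosome, so the picking itself may have changed the sex make-up. In WT roX1 reached at most 300.2 CPM, against at least 524.6 in elav null, 732.7 in the double null and 709.6 in WDd. For roX2 the highest WT value was 8.61 CPM, and the lowest in these groups were 37.02, 34.17 and 19.55 CPM. As far as these 2 genes report sex, it was confounded with genotype in each comparison with WT. Sex make-up is argued against as the main source by the 1861 of 2479 elav null calls (75.1%) and 79.8% of the double null calls that appeared mirrored against WDd, where 20 simulations with WDd at the mean of the null group gave at most 0.0725%, though roX2 was lower in WDd than in both (log2 −1.13 and −0.87, edgeR adjusted p = 0.00556 and 0.02) and roX1 was not called (0.20 and −0.26), so a part from sex stays open. The FM7 chromosome is argued against as the main source for these groups by way of X-linked genes, whose odds ratio among the calls had an upper 95% bound of at most 1.13. It is not argued against for WDd, where the odds ratio was 5.4. Among so many calls the ratio cannot exclude an FM7 effect on some X-linked genes. Of the 14 X-linked WDd calls, 11 were called in the same direction in both null groups. Delay cannot be told apart: against it, in elav null and the double null, lay the midgut medians of 0.642 and 0.246 and the cell cycle medians of −0.385 and −0.419, its way lay those of cuticle (−1.92 and −1.83) and neuroblast genes (1.03 and 2.02), and none of these lists passed with an estimated correlation (adjusted p = 0.392 and 0.565, 0.998 and 0.985, 0.217 and 0.29, 0.671 and 0.264; only 1 neuroblast gene rose in elav null without the library labelled elav null replicate 3, WT replicate 1 or WT replicate 2, and 5 without elav null replicate 1), while the mid-embryo patterning list had a median of 0.413 in the double null (3 of 14 genes called higher, unadjusted camera p = 0.0226, 0.0416 with an estimated correlation) and in WDd the midgut, cell cycle and neuroblast medians (−0.417, 0.468 and 0.432) lay its way and cuticle did not move (−0.0184). Older age stays open too, as no age series sets a scale for the cuticle median of −1.92, and loss of elav and fne themselves stays open, untested. The WT libraries also differed among themselves. In WT replicates 1 to 3 TwdlM stood at 980.9, 690.9 and 191.5 CPM and Cpr65Ea at 258.2, 213.4 and 8.87 CPM. Cpr78Cc moved less (384.4, 324.7 and 283.3 CPM), and elav ran the other way (68.57, 109.5 and 160.5 CPM). Whether these libraries differed in age was not tested.

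The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. In edgeR the real split called 2479 genes for elav null against WT (highest other split 0), 2998 for the double null (0), 28 for WDd (2), 2356 for WDd against elav null (0) and 2933 for WDd against the double null (0). In these 5 comparisons 1 split, the real one, reached the real count. For the double null against elav null the real split called 32 genes and 3 of the splits reached as many. Elav null replicate 1, the library labelled elav null replicate 3 and double null replicate 2, which detected the fewest genes, against the rest gave 193 genes, and elav null replicates 1 and 2 with double null replicate 2 gave 86. These counts point to a structure of the samples other than their groups.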

How the results depend on the processing

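Robust dispersion, the fit without the 3 libraries that detected the fewest genes (below: without 3 libraries) and the similarity over genes of at least 5 CPM were tests chosen only after the result was seen, and the other alternatives were planned. The numbers of genes called in elav null and in the double null against WT, and in WDd against either, stayed within 1.5 times with RLE factors, without a low-count filter, with a replicate block and with robust dispersion. With robust dispersion the WDd and double null against elav null counts stayed within 1.5 times as well. Of the results for lists and named genes under all alternatives, 3226 kept their direction and side of the threshold, 388 lost a call, 8 gained one and 1 reversed. These totals include the fit without 3 libraries, in which elav null was replicate 2 alone. The reversed result was the axon guidance list in WDd against WT, whose camera p was 5.82e-09 (WT replicate 3) to 0.954 (reversed, WT replicate 1) without single libraries. The cause was not tested.

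Fitting only the 6 libraries compared gave 450 genes higher and 823 lower in elav null, and 1784 lower in WDd against the double null. DESeq2 gave 1450 higher in elav null, 1690 higher in the double null, 58 higher and 97 lower in WDd, and 1552 and 1874 lower in WDd against elav null and the double null. A 2-fold minimum, which by construction only removes genes, left 481, 533, 478 and 536 for elav null higher, double null higher and WDd lower against elav null and the double null. Without 3 libraries, none of them WT or WDd, WDd had 24 genes higher and 63 lower against WT, and 1552 lower against the double null. With the block, WDd had 5 higher and 11 lower. Other than for the 2-fold minimum, the cause was not tested.

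The double null against elav null changed most often. edgeR called 1 higher and 6 lower with RLE factors, 40 lower without the filter, 0 and 2 with the block, 86 and 349 without 3 libraries, and 0 and 0 with only the 6 libraries. With all libraries 1836 genes had an unadjusted p under 0.05, and DESeq2 called 257 higher and 320 lower. Leaving out single libraries of these groups gave 0 (each double null library) to 321 (without the library labelled elav null replicate 3) higher and 0 (double null replicates 2 and 3) to 726 lower (without the library labelled elav null replicate 3). The remaining counts were 1 and 2 without elav null replicate 1, 64 higher without elav null replicate 2 and 2 lower without double null replicate 1. Counts without a WT or WDd library are in the report. The cause was not tested beyond the library labelled elav null replicate 3.

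Leaving out single libraries of the groups compared, which also lowers the number of samples, gave 493 (WT replicate 2) to 855 genes higher in elav null and 602 (WT replicate 2) to 901 in the double null. WDd had 0 (WDd replicate 1) to 14 (WT replicate 1) higher and 3 (WDd replicate 2) to 21 lower against WT in edgeR, where 644 genes had an unadjusted p under 0.05 with all libraries. Higher counts of 2, 4, 2 and 2 came without WT replicates 2 and 3 and WDd replicates 2 and 3, and lower counts of 7, 12, 4 and 6 without WT replicates 2 and 3 and WDd replicates 1 and 3. Against elav null WDd had 957 (WDd replicate 3) to 1601 higher and 486 (WDd replicate 3) to 866 lower, with 528 and 535 lower without WDd replicates 1 and 2. Against the double null 557 (WDd replicate 3) to 789 were lower, with 615 without double null replicate 1. Leaving out a library of another group reached beyond these ranges: 871 higher in elav null (double null replicate 2), 1026 and 1292 higher in the double null (elav null replicate 1 and the library labelled elav null replicate 3), 1642 higher and 879 lower in WDd against elav null (double null replicate 2), and at most 1344 lower against the double null (the library labelled elav null replicate 3). For WDd against WT it gave 24 higher and 54 lower without the library labelled elav null replicate 3, 23 lower without elav null replicate 1 and 11 lower without double null replicate 3. The cause was not tested. A group reduced to 2 libraries was fitted with the spread pooled over all groups.

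The correlation of fold changes between elav null and the double null was 0.483 without the filter and 0.87 over genes of at least 5 CPM. It was 0.303 (elav null replicate 2) to 0.62 without single libraries, with 0.492 without the library labelled elav null replicate 3. Between elav null and WDd it was 0.19 without the filter and 0.0799 to 0.262 (WT replicate 1) without single libraries, with 0.255 without WT replicate 3 and 0.158 without elav null replicate 2. Between the double null and WDd, at −0.00403, where unchanged groups gave 0.326 in simulations that share WT, it was above 0 without the filter (0.107), over genes of at least 5 CPM (0.0689), without WT replicates 1 or 3 (0.191 and 0.299), double null replicates 1 or 3 (0.0208 and 0.0451) or WDd replicate 3 (0.00869), and was lowest at −0.0755 without WDd replicate 2. The simulated level cannot show that these 2 groups were less alike than unchanged ones, for the reason given in the report. The cause was not tested. Replicate numbers did not pair the samples: after removing group means, libraries of 1 number correlated at −0.0299 on average (−0.24 to 0.242) and of different numbers at 0.0151. Depth limits the smallest library to 0.133 CPM at 3 counts.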

Other observations

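The families by gene symbol and the 4 lists of this part were tests chosen only after the result was seen, and the p-values of the families are adjusted over the 33 tests of 11 families in the 3 mutants against WT.

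In 2 families of protein synthesis the calls of both null groups were all lower, but neither family passed with an estimated correlation. Of 72 mitochondrial ribosomal protein genes, 31 fell and none rose in elav null (median log2 −0.929, camera p = 2.79e-08, adjusted p = 0.834 with an estimated correlation). In the double null 52 fell and none rose (−1.35, camera p = 4e-15, adjusted p = 0.52 with an estimated correlation). The number in elav null was 11 without WT replicate 1, 12 without WT replicate 2 and 20 without elav null replicate 2. In WDd edgeR called none (−0.248, camera p = 0.000486, adjusted p = 0.834 with an estimated correlation). Of 33 aminoacyl-tRNA synthetase genes, 12 fell in elav null (−0.55, camera p = 0.00296, adjusted p = 0.52 with an estimated correlation) and 17 in the double null (−0.664, camera p = 0.000156, adjusted p = 0.441 with an estimated correlation). The latter number was 10 without WT replicate 2 and 9 without double null replicate 3. WDd had no call in this family and a median of −0.323 (camera p = 8e-11, adjusted p = 0.32 with an estimated correlation).

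Detoxification genes moved both ways. Of 83 cytochrome P450 genes 16 rose and 10 fell in elav null, and 20 rose and 12 fell in the double null (camera p = 0.0121 and 0.0171, upward, adjusted p = 0.441 with an estimated correlation in both). The number that fell in elav null was 17 without the library labelled elav null replicate 3, and the number that rose in the double null was 12 without WT replicate 2 and 13 without WT replicate 3. The 138 chemosensory receptor genes had a camera p of 0.0162, upward, in the double null, with 1 call (adjusted p = 0.834 with an estimated correlation). In WDd camera p was 0.0167 for P450, 0.0154 for UDP-glycosyltransferase and 0.0477 for tetraspanin genes, upward, and 0.0121 for mucin and 0.0167 for proteasome genes, downward. With an estimated correlation these were adjusted p = 0.441, 0.441, 0.834, 0.441 and 0.834, and 1 mucin gene was called. Osiris, glutathione S-transferase and odorant-binding protein families did not pass camera in any mutant, although single members were called. Of 35 glutathione S-transferase genes 7 rose and 7 fell in each null group, of 38 odorant-binding protein genes 4 rose and 2 fell in each, and of 23 Osiris genes 3 fell in elav null and 1 in the double null.

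Of 13 eggshell and yolk genes tested, 8 rose in elav null (unadjusted camera p = 0.000108, 0.165 with an estimated correlation), as the single-library levels in the report describe. The summed level of 7 adult flight muscle and head genes was 176.4 CPM in elav null replicate 2, 31.6 in replicate 1, 4.37 in the library labelled elav null replicate 3 and 12.9 to 20.5 elsewhere (unadjusted camera p in elav null 0.192). The summed level of 17 maternal and germline genes was 854.5 CPM in WDd replicate 2 and 336.6 to 535.8 elsewhere (unadjusted camera p in WDd 0.000436, 0.237 with an estimated correlation). That of 14 patterning and neurogenesis genes of the mid-embryo was 131.9 to 147.4 CPM in the double null and 89.9 to 110.0 elsewhere (3 of 14 called higher, unadjusted camera p 0.0226, 0.0416 with an estimated correlation). For these values no explanation was tested.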
